A study of Escherichia coli str. K-12 substr. MG1655 with 35 samples.

How the data were processed

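Chromosome conformation capture followed by sequencing (3C-seq) was measured in 33 libraries of Escherichia coli K-12 MG1655, and RNA in 2 libraries of stationary wild-type cells. In 3C-seq, cells are fixed with formaldehyde, their DNA is digested with a restriction enzyme and religated in dilute solution, and each sequenced junction counts a contact between a pair of chromosomal places. The enzyme was HpaII, and fixation was in 7% formaldehyde except for replicate 2 of wild type in minimal medium at 30 °C, which was fixed in 3%, per the labels' protocols. Samples were grouped by strain, medium, temperature, growth phase and plasmid, as the titles give them. This made 20 groups of contact maps, 1 with 3 libraries, 11 with 2 and 8 with 1. Libraries whose titles carry no replicate number are called replicate 0. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

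Each contact map was deposited as a symmetric matrix of whole-number contact counts between 928 bins of 5 kb, with no normalization visible in the values. Bowtie2 is the mapper named by the submitters' processing notes, without a version, and the genome build, read filters and assignment of reads to bins are not given in the sources used here. Ribosomal RNA operons are near-identical repeats, so values of their bins may depend on how reads matching several copies were assigned. The matrices came in a pair of layouts, 25 separated by tabs and 8 by spaces. The 8 spaced files differed from the others in their self-contacts, and 2 of them held odd numbers on the diagonal, so the layouts were treated as possible processing batches. The RNA files were deposited as whole-number counts per 5 kb bin. Whether these count reads or summed coverage, and how strand and ribosomal RNA were handled, is not given in the sources used here, so RNA values are reported as shares of the library and called RNA signal. No genome sequence was used here. Gene names were placed on bins with the RefSeq gene table of assembly ASM584v2, which served only for names and neighbourhood, and all 91 listed genes were matched. A gene was assigned to the bin of its start and the bin before it, because the build of the files is unknown. The value given for a listed gene is that of whichever of these bins had the smaller p, so it can belong to the bin beside the gene, and a gene named at a bin starts in it or in the next.

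Contacts closer than 10 kb were left out of all tests, which kept 987613 to 11300774 contacts per library. Contacts were summed over 93 segments of 50 kb and 4 classes of separation, 10 to 100 kb, 100 to 280 kb, 280 to 1000 kb and over 1000 kb. The terminus region, called Ter below, was set at 1.1 to 1.9 Mb, which is 16 segments and 160 bins. Its bounds were to come from the matS motif, the site that MatP binds, but no genome was at hand and the alternative that needs the motif was not run. Each class was tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) in one fit over all 33 libraries, with 13 residual degrees of freedom and the segment's total contacts of at least 10 kb as an offset. This offset removes depth and the segment's own copy number, but not differences in copy number among the places it contacts. A change is a change in the share of a segment's contacts that falls in the class, and a changed ratio of origin to terminus can still enter it. Groups of 1 library are assumed to vary like the others. Benjamini-Hochberg adjustment was made over the 93 segments of a class, with a threshold of 0.05. The 280 to 1000 kb class was the main outcome and is called long-range below. Local contacts, at 10 to 50 kb, were tested in the same way per 5 kb bin, relative to the share at that separation over the whole library. Before the data were examined, the tests, their alternatives, 7 gene lists and the rule for naming places were fixed. That rule takes merged runs of segments and up to 5 segments of largest change each way, the 10 bins of largest local rise and fall, the 15 bins of highest RNA signal, and up to 4 members per gene list. Lists were tested by the mean change over their places against every rotation of the bins around the chromosome, with adjustment over the 28 tests of 7 lists in 4 comparisons. The list of ribosomal protein and RNA polymerase operons, also called ribosomal protein operons below, includes the ATP synthase gene atpB.

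Balanced maps were made by iterative correction of at most 200 rounds. On these, the contact within Ter at 280 to 600 kb over that outside Ter was compared by an exact permutation test within strata of temperature and mukB. Correlations across bins were tested by rotations of at least 20 bins, since neighbouring bins are not independent. Overlaps across bins were tested by every rotation, and the correlation across segments by 92 rotations. Rotation tests were two-sided, except that for gene lists among the bins of highest RNA signal, which was one-sided. Domain borders were minima of the contact between 50 kb squares either side of a bin, with a prominence of at least 0.1 on the log2 scale. The ratio of origin to terminus counts the mean contacts per bin within 250 kb of the gene next to the replication origin, mnmG, over that within 250 kb of hipA, next to the dif site. Shares of single libraries carry 95% Wilson intervals over contact ends, which cover counting error only. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

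The count models were tested on simulated data made from the real means and library sizes. Each comparison was drawn a single time, with independent counts and changes at random places, higher and lower in turn. A change shared by a whole region, such as Ter, was not simulated. For matP against wild type at 30 °C, 30 of 93 segments were changed, split over 3 folds. Of those at 1.1-, 1.25- and 1.5-fold, 10%, 60% and 100% were recovered. For the single matPdC20 library these shares were 0%, 20% and 80%. For local contacts of hns, 200 changed bins among 928 were split over these 3 folds, and 37.3%, 95.5% and 100% of those at each fold were recovered, with 4 false calls of 159. All 14 pairs of replicates differed by more than sampling noise, with chi-square per degree of freedom from 24.8 to 502, so each library counted as 1 replicate.

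Alternatives were DESeq2 1.42.0 with the same offsets, library totals with edgeR's TMM factors, limma 3.58.1 on balanced maps, other class bounds, a minimum separation of 25 kb, removal of bins of low coverage, fits of only the groups compared, and leaving out each replicate. The TMM alternative scales whole libraries and does not remove copy number, so it also carries changes of the ratio of origin to terminus. The low coverage filter, at 0.5 times the median bin in any library, removed 213 bins, 133 of them among the 160 bins of Ter. Added after seeing the data were totals without contacts over 1000 kb, removal of 54 locally low bins (under 0.5 times the running median of 41 bins in any library), removal of the first bin, fits on tabbed files alone, and fits with the file layout as a term beside the groups. The planned test of plasmid contacts, with its alternatives, was not run because the matrices held no separate plasmid bin.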

Results

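The series maps the folding of the Escherichia coli chromosome in wild-type cells, in strains lacking nucleoid-associated proteins (fis, hns, and hupA with hupB), the condensin subunit gene mukB or the terminus-organising gene matP, and in growing or stationary cells. Exponential cultures in minimal medium at 30 °C gave 3 wild-type, 2 matP, 1 matPdC20, 1 zapB and 2 fis libraries. At 22 °C there were 2 wild-type libraries, 2 labelled mukB, 1 mukBmatP and 1 matP. Rich LB medium gave 2 wild-type and 2 hns libraries at 30 °C and 2 wild-type and 2 hupAB libraries at 37 °C. Strains carrying the plasmid pGBM2, or pGBM2 with 5 matS sites, made up 8 libraries in wild type, matPdC20 and zapB at 30 °C, and stationary wild type gave 2 contact maps and 2 RNA libraries. The matrices summed to 2112202 to 24478990, with a median of 5572920, and the RNA libraries to 19444153 and 18427390.

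The deleted genes were looked at first. MukB is the core subunit of the MukBEF condensin, and its gene covers most of the bin at 975001 to 980000. In the mukBmatP library this bin had 0.131 of the contacts of the bins around it. The 2 libraries labelled mukB had 0.793 and 0.839, inside the range of 0.676 to 0.914 of the 30 libraries not labelled mukB, so the label was not borne out by this bin and the comparison is written below as that of the libraries labelled mukB. Genes matP, fis, hns, hupA, hupB and zapB are far shorter than 5 kb and could not be checked in this way. The genotype label of matP replicate 0 at 30 °C lists no matP deletion although its title names the mutant. Its long-range share within Ter, 32.5%, lay near that of replicate 1, 35.0%, and above the 19.2% to 20.9% of the 3 wild-type libraries.

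**Figure D1:**
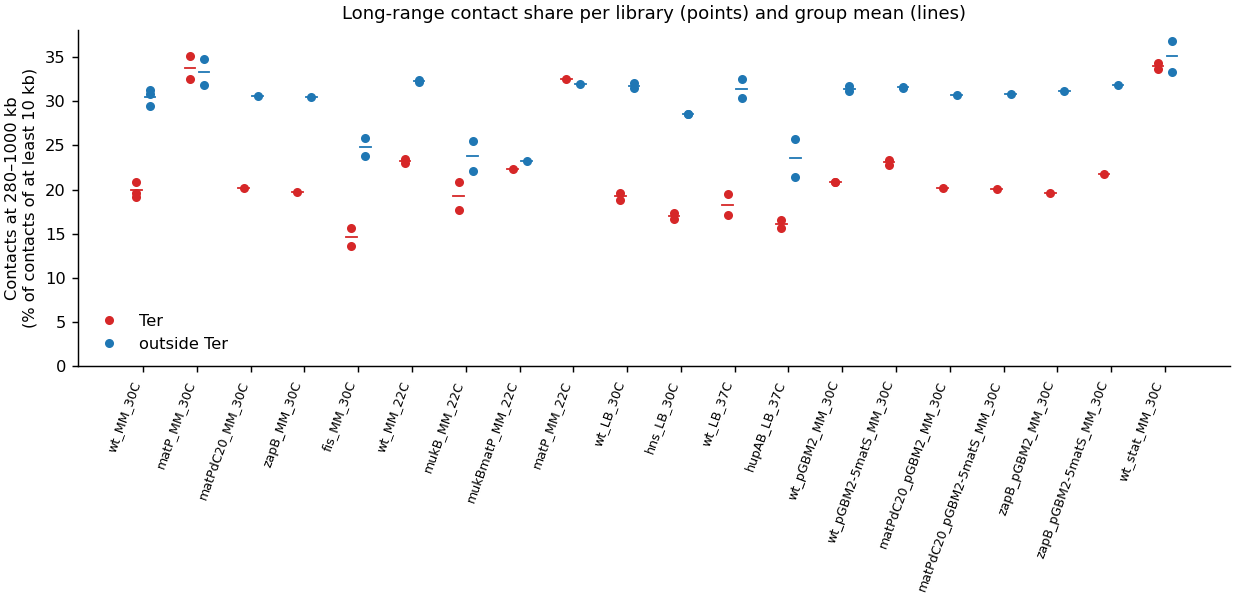
Share of contacts of at least 10 kb that lie 280 to 1000 kb apart, in percent, for Ter (red) and the rest of the chromosome (blue), with one point per library and a line at the mean of each group. Wild type at 30 °C sits at 19.9% in Ter against 30.5% outside, and matP at 33.8% against 33.3%.

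MatP binds matS sites and organises the terminus into a separate macrodomain. Without matP at 30 °C, Ter gained long-range contacts. The share of its contacts at 280 to 1000 kb was 33.8% ± 1.81 (SD, n = 2) against 19.9% ± 0.862 (SD, n = 3) in wild type, while the rest of the chromosome had 33.3% ± 2.08 (SD, n = 2) against 30.5% ± 0.922 (SD, n = 3). All 16 Ter segments rose, by a mean of 0.78 on the log2 scale or 1.72-fold, and the mean outside was 0.14. The rise formed a single run of 34 segments from 700001 to 2400000. The peak was at 1650001 to 1700000, with a log2 fold change of 1.12 (SE 0.11, edgeR adjusted p = 2.99e-06), followed by 1600001 to 1650000 with 1.09 and 1700001 to 1750000 with 1.07. The share at 10 to 100 kb, of the same total, moved the other way and fell in 9 Ter segments, with a Ter mean of -0.71. Removing bins of low coverage, which takes out 133 of the 160 Ter bins, left 2 segments past the threshold and a mean of 0.30 over the rest of Ter, and without matP replicate 1 the count was 17. The matP maps were both in tabbed files, as were 2 of the wild-type maps.

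**Figure D2:**
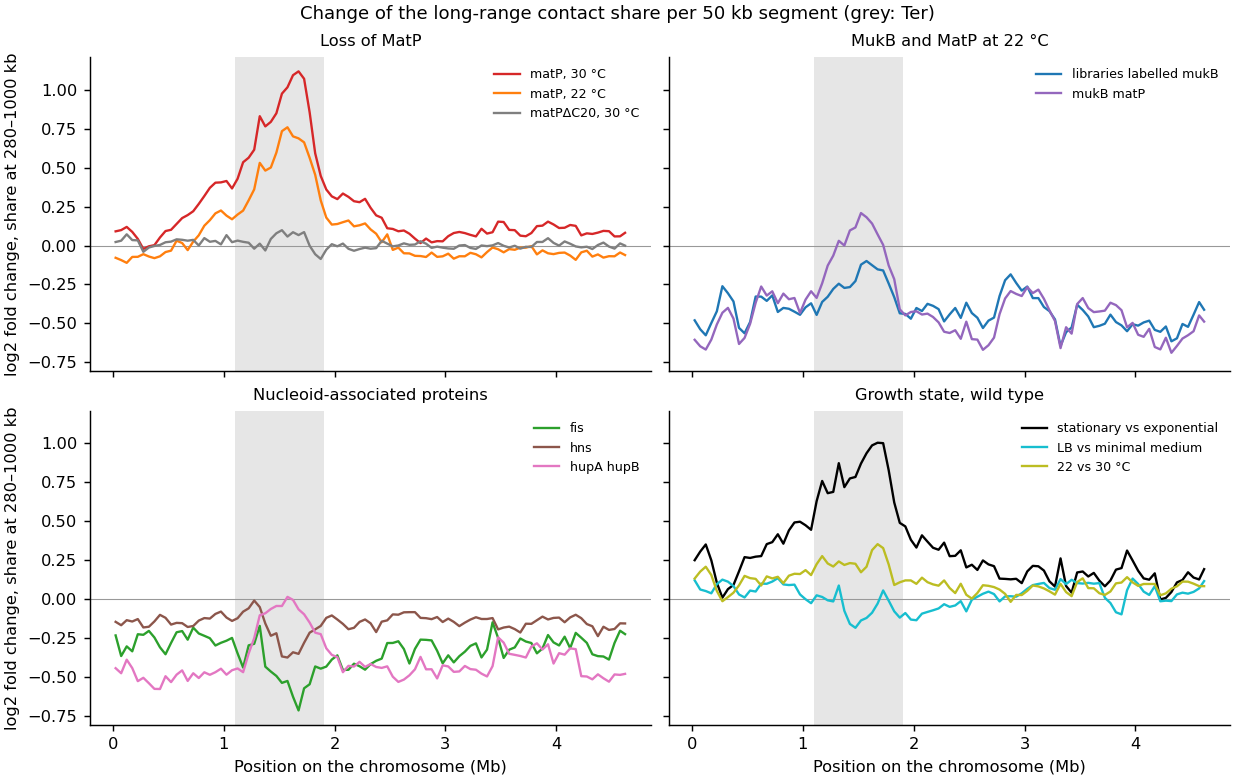
Log2 fold change of the long-range share (280 to 1000 kb) per 50 kb segment along the chromosome in Mb, with Ter in grey. Lines are the fitted changes against the matching wild type, and the matP and stationary profiles peak inside Ter at 1.12 and 1.00.

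The matPdC20 strain, whose name denotes a MatP without its last residues, and zapB, which lacks a division protein known to link MatP to the septum, had long-range shares in Ter near those of wild type. The share was 20.1% (95% Wilson interval 20.0 to 20.2) in matPdC20 and 19.7% (19.6 to 19.8) in zapB, against 19.2% to 20.9% in wild type. Ter means of the log2 change were 0.03 and -0.01, with a median SE of 0.11 per segment. In each comparison edgeR placed 0 segments past the threshold, with 0 at an unadjusted p under 0.05 and 0 by DESeq2. On balanced maps, contact within Ter at 280 to 600 kb was -0.54 in matPdC20, above the 3 wild-type libraries (-0.66 to -0.62), and matPdC20 was also higher by 0.06 with pGBM2 and by 0.07 with 5 matS sites, a pair that differs in file layout. A test chosen after these values were seen restates them, with a mean difference of 0.08 (two-sided exact permutation p = 0.028, the smallest of 36 arrangements). Contact from Ter to its outside went the other way, at -0.74 in matPdC20 against -0.71 to -0.66 in wild type, -0.75 against -0.67 and -0.62 with pGBM2 and -0.71 against -0.38 and -0.32 with 5 matS sites, whereas both measures rose in matP. On simulated data with scattered changes, a single matPdC20 library recovered 80% of changed segments at 1.5-fold and 0% at 1.1-fold. A change over the whole of Ter was not simulated.

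At 22 °C, loss of matP was again followed by a rise in Ter. The single matP library had 32.6% long-range contacts in Ter (95% Wilson interval 32.4 to 32.7) against 23.2% ± 0.324 (SD, n = 2) in wild type. A run of 11 segments from 1300001 to 1850000 rose, with a mean log2 change of 0.61, and none rose outside Ter. The highest was 1550001 to 1600000, at 0.76 (SE 0.15, edgeR adjusted p = 0.0070). The count was 0 without wild-type replicate 0, 7 without replicate 1, 0 without low coverage bins and 0 with totals that leave out contacts over 1000 kb. The mean of all Ter segments was 0.50, 0.24 without low coverage bins and 0.47 with those totals, so with the totals the change kept its size. Within the spaced layout, which holds the matP map and 1 wild-type map, the change was 0.50 in Ter and -0.02 outside. The interaction of matP with temperature was negative in Ter, with a mean of -0.28, and passed in 0 segments by edgeR, with 1 at an unadjusted p under 0.05 (DESeq2 was not run on interactions).

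Across strata, contacts within Ter at 280 to 600 kb, relative to those outside, were higher where MatP was lost. The balanced contact in Ter was -0.64 ± 0.02 (SD, n = 3) on the log2 scale in wild type at 30 °C and 0.12 ± 6.5e-04 (SD, n = 2) in matP. The differences were 0.76 at 30 °C, 0.57 at 22 °C and 0.17 between mukBmatP and the libraries labelled mukB. Their mean was 0.50, with an exact permutation p of 0.011 (two-sided, 90 arrangements), the smallest these arrangements allow. An alternative grouped matPdC20, whose name denotes a shortened MatP, with the strains that lost MatP, and added its plasmid strata. The difference was then smaller, at 0.28 (exact permutation p = 6.2e-04, the smallest that 1620 arrangements allow). That p is lower because there are more arrangements. Contacts from Ter to its outside at the same separation also rose in matP, by 0.66 at 30 °C and 0.52 at 22 °C.

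In the libraries labelled mukB, long-range contacts fell over most of the chromosome, and the segments from 1450001 to 1750000, inside Ter, did not pass the threshold. The share outside Ter was 23.8% ± 2.44 (SD, n = 2) against 32.3% ± 0.219 (SD, n = 2) in wild type at 22 °C, a mean log2 change of -0.44, while Ter changed by -0.26. The fall covered 86 of the 93 segments, in runs from 1 to 1300000, 1350001 to 1450000 and 1750001 to 4640000. The deepest was 3300001 to 3350000, at -0.64 (SE 0.13, edgeR adjusted p = 6.0e-04), then 4300001 to 4350000 at -0.62. Within the spaced layout the change outside Ter was -0.55 and in Ter -0.37, and within the tabbed layout -0.33 and -0.17. A fit on tabbed files alone placed 0 segments past the threshold, with 52 lower at an unadjusted p under 0.05, and a fit of only these 2 groups placed 20, with the means unchanged at -0.44 outside and -0.26 in Ter. Whether the fall differed between Ter and its outside was not tested.

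In mukBmatP, which lacks both proteins, segments outside Ter lost long-range contacts and most of Ter did not pass the threshold. The log2 change was -0.47 outside and -0.04 in Ter, where the share was 22.3% (95% Wilson interval 22.2 to 22.5), and 78 segments fell, 2 of them in Ter. The runs were 1 to 600000, 650001 to 1150000 and 1850001 to 4640000, and the deepest segment was 4300001 to 4350000, at -0.69 (SE 0.13, edgeR adjusted p = 5.9e-04). For the class of 200 to 800 kb, 49 segments were lower. Against the libraries labelled mukB, mukBmatP differed by 0.21 in Ter and -0.04 outside, with 0 segments past the threshold by edgeR, 4 higher at an unadjusted p under 0.05 and 0 by DESeq2. The interaction of matP with mukB had a Ter mean of -0.29 and passed in 0 segments by edgeR, with 3 lower at an unadjusted p under 0.05.

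Fis is an abundant nucleoid-associated protein of fast-growing cells that activates ribosomal RNA promoters. Without it, long-range contacts fell along nearly the whole chromosome, in 89 of 93 segments, and the deepest were in Ter. The share in Ter was 14.6% ± 1.41 (SD, n = 2) against 19.9% in wild type, and the mean log2 change was -0.46 in Ter and -0.31 outside. The deepest segments were 1650001 to 1700000 at -0.71 (SE 0.12, edgeR adjusted p = 9.2e-04), 1600001 to 1650000 at -0.63 and 1700001 to 1750000 at -0.57. Runs of lower segments were 1 to 600000, 650001 to 1300000, 1350001 to 3400000, 3450001 to 3900000 and 3950001 to 4640000. The count was 27 without fis replicate 0, 59 with TMM and 37 with totals that leave out contacts over 1000 kb, when the means were -0.41 in Ter and -0.34 outside.

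Local contacts in fis, relative to the whole library, rose in 17 bins and fell in 28, and with TMM the split was 6 and 56. The rise was a block around recB, recC and recD, the exonuclease V genes, with thyA and galR. It covered 2940001 to 2985000, with a maximum of 0.38 at 2955001 to 2960000 (SE 0.06, edgeR adjusted p = 1.57e-04). The only other named rise was 1375001 to 1380000, at 0.20. The falls covered 3425001 to 3445000, from the 16S ribosomal RNA gene rrsD to the ribosomal protein genes at rpsM, with -0.58 to -0.79. They also covered 4170001 to 4180000 at tufB, rplK and rpoB (-0.33 and -0.42), 1300001 to 1315000 from oppA to tonB (-0.34 to -0.51) and 3925001 to 3930000 at asnA and mioC beside the origin (-0.31). Of these named falls, 4 were bins of locally low coverage, and all 10 kept their sign and passed with TMM, against 3 of the 10 named rises. Ribosomal protein and RNA polymerase operons fell in 6 of 13 places and rose in 0, or 7 adjusted over the list alone, with a mean of -0.21 (rotation p adjusted 0.0302), which was -0.48 with TMM and -0.14 without locally low bins. Ribosomal RNA operons fell in 2 of 7, rrsD and rrsC, or 4 adjusted over the list alone, with a mean of -0.20 (adjusted 0.0302), which was -0.30 with TMM and -0.12 without locally low bins. Since the assignment of reads from repeated operons is not known, a change of contacts at the operons themselves is not established. Among the other lists, H-NS silenced loci had 1 lower place of 19 (bglG), or 2 adjusted over the list alone, stationary phase genes 1 higher of 17 (rpoS at 0.17), or 0 adjusted over the list alone, and prophages, flagellar operons and abundant small RNAs 0, with adjusted rotation p from 0.50 to 0.99. The local count in fis was 10 without fis replicate 0, 17 without fis replicate 1, 29 without wild-type replicate 2, 28 in a fit of only the 2 groups and 80 for contacts at 10 to 100 kb.

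H-NS coats AT-rich, horizontally acquired DNA and silences it. Without it, long-range contacts were at 17.0% ± 0.477 (SD, n = 2) in Ter against 19.2% ± 0.601 (SD, n = 2) in wild type in LB at 30 °C, a mean log2 change of -0.20, and of -0.14 outside. By edgeR 0 segments passed, with 13 lower at an unadjusted p under 0.05 and 2 lower by DESeq2, while 33 were lower with TMM and 1 for the class of 200 to 800 kb.

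Local contacts changed in 192 bins of the hns map, 94 higher and 98 lower, and 39 of the higher bins were in Ter. The loci that H-NS is known to silence rose as a group by the main scaling, in 12 of 19 places with 1 lower (13 and 1 adjusted over the list alone) and a mean of 0.21 (rotation permutation p adjusted 0.0302). Without low coverage bins the mean was 0.13 over 14 places, 8 of them with a higher bin, but with TMM 3 places had a higher bin and 7 a lower bin, and the mean was -0.11 (rotation permutation p = 0.114). Members were ydeO, an acid resistance regulator (0.71), waaQ of lipopolysaccharide core synthesis (0.56), cadC, the activator of lysine decarboxylase (0.45), and the glutamate decarboxylase gadA (0.42). With TMM ydeO, which lies in Ter, stayed higher, at 0.42, and waaQ, cadC and gadA, outside Ter, turned negative without passing. As set out below, TMM carries the ratio of origin to terminus in hns, with a median of 0.18 in Ter and -0.09 outside. These TMM values are thus no separate evidence for or against a change at these places. Prophage places rose in 2 of 9, intF and ydfK, with a mean of 0.14 (adjusted 0.0483), also 2 adjusted over the list alone, that was 0.06 without low coverage bins and -0.02 with TMM, where intF turned negative. The 10 named rises also included 2780001 to 2785000 at pinH (0.78), 1215001 to 1220000 at ycgZ and ymgA (0.77), 2105001 to 2110000 in the rfb cluster (0.58) and 3650001 to 3655000 at hdeA and hdeB (0.57), of which the first and the last turn negative with TMM. Of the named rises, 9 were bins of locally low coverage.

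The named falls in hns mostly passed with both scalings. TMM also carries the lower ratio of origin to terminus in hns, 2.30 against 2.94 in wild type. Its median local change was -0.09 outside Ter and 0.18 in Ter. Passing with TMM is thus not separate support for falls near the origin, such as those at atpB, rrsC and rrsA. Ribosomal RNA operons fell in 5 of 7 places and rose in 0, also adjusted over the list alone, with a mean of -0.18 (rotation p adjusted 0.0302), which was -0.41 with TMM. As in fis, the unknown assignment of reads from repeated operons leaves open whether contacts of the operons themselves changed. Named falls were 1305001 to 1310000 at oppF and tonB (-0.40, SE 0.06, edgeR adjusted p = 1.56e-04), 210001 to 215000 at nlpE (-0.32), 1295001 to 1305000 from adhE to oppD (-0.32 and -0.28), 4030001 to 4035000 at rrsA (-0.30), 3930001 to 3940000 at rbsD and rrsC (-0.30 and -0.28), 3920001 to 3925000 at the ATP synthase gene atpB (-0.29), 1315001 to 1320000 at the tryptophan operon (-0.27) and 4200001 to 4205000 at hupA (-0.27). With TMM 9 of the 10 named bins passed in the same direction, all but the tryptophan operon (-0.07). Ribosomal protein operons had 5 lower places of 13, stationary phase genes 3 higher and 3 lower of 17, small RNA and envelope genes 1 lower of 8 (ompF) and flagellar operons 0 of 5, the same counts as those adjusted over the list alone, with adjusted rotation p from 0.78 to 0.87. The lower places of the ribosomal protein list included the ATP synthase gene atpB (-0.29). With TMM ribosomal protein operons had a lower bin in 7 places and a mean of -0.26 (rotation permutation p = 0.044), against -0.04, and flagellar operons a higher bin in 4, with a mean of 0.24 (rotation permutation p = 0.137). The acid chaperone gene hdeB, among the stationary phase genes, was higher at 0.35 but lower with TMM, at -0.26 (edgeR adjusted p = 0.046). The count of changed bins was 28 without hns replicate 1, 123 without hns replicate 0, 44 without wild-type replicate 0, 290 in a fit of only the 2 groups and 328 with TMM.

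HU, the product of hupA and hupB, is a non-specific DNA-binding protein. In hupAB at 37 °C, long-range contacts fell outside Ter and, by the main scaling, changed less within it. The share outside was 23.6% ± 2.98 (SD, n = 2) against 31.4% ± 1.503 (SD, n = 2) in wild type, with mean log2 changes of -0.44 outside and -0.16 in Ter. With TMM the order was the other way, -0.32 outside and -0.58 in Ter. TMM also carries the ratio of origin to terminus, 5.95 in hupAB against 3.42 in wild type, so that order is not separate evidence. A difference between Ter and its outside was not tested. The runs were 1 to 1300000 and 1850001 to 4640000, 82 segments in all, with the deepest at 400001 to 450000 (-0.58, SE 0.09, edgeR adjusted p = 1.82e-04). Contacts at 100 to 280 kb rose in 67 segments and fell in 7, all 7 in Ter. A fit of only these 2 groups placed 0 long-range segments past the threshold, with 9 at an unadjusted p under 0.05 and the means unchanged at -0.44 outside and -0.16 in Ter.

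Local contacts in hupAB rose in 95 bins and fell in 96, and with TMM in 266 and 236. No bin rose in Ter and 48 fell there, or 156 with TMM. TMM also carries the higher ratio of origin to terminus in hupAB, 5.95 against 3.42 in wild type. Its median local change was -0.66 in Ter and 0.11 outside. Passing with TMM is thus not separate support for falls in Ter. All 10 named falls were in Ter and passed with TMM as well. They were led by 1570001 to 1575000 at gadB (-0.42, SE 0.10, edgeR adjusted p = 0.0061), 1315001 to 1320000 at the tryptophan operon (-0.42), 1450001 to 1455000 at the phenylacetate genes paaA to paaE (-0.40), 1305001 to 1310000 at oppF and tonB (-0.39) and 1325001 to 1330000 at the topoisomerase gene topA (-0.38). The Rac prophage genes intR and recT fell by 0.35. Named rises included 3185001 to 3190000 at yqiG and insC5 (0.40), 380001 to 385000 at yaiP (0.39), 310001 to 315000 at ecpA (0.37), nrfE (0.33), intF (0.33), tsr (0.30) and rrsD (0.30), and 5 of the 10 passed with TMM. Lists went both ways, with H-NS silenced loci 3 higher and 3 lower of 19, prophages 1 and 3 of 9, ribosomal protein operons 1 and 3 of 13, ribosomal RNA operons 1 and 1 of 7, stationary phase genes 1 and 2 of 17, flagellar operons 0 and 1 of 5, and small RNA and envelope genes 1 and 0 of 8. Adjusted over the list alone, ribosomal RNA operons had 2 and 2 and stationary phase genes 1 and 1, and the other lists had the same counts. Adjusted rotation p ranged from 0.78 to 0.99. With TMM prophages had a mean of -0.27 (rotation permutation p = 0.013) instead of -0.01. Places with a higher and a lower bin were then 4 and 0 for ribosomal RNA operons, 2 and 0 for ribosomal protein operons, 0 and 4 for flagellar operons (mean -0.30), 6 and 7 for stationary phase genes, 5 and 4 for H-NS silenced loci and 1 and 3 for small RNA and envelope genes. The count of changed bins was 108 and 83 without wild-type replicates 0 and 1, 126 and 110 without hupAB replicates 0 and 1, and 299 for contacts at 10 to 100 kb.

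Stationary wild-type cells were compared with exponential cells in the same medium. The share of short-range contacts fell everywhere, in 93 of 93 segments at 10 to 100 kb and 79 at 100 to 280 kb. The share over 1000 kb rose in 91. These are shares of the same total, so the falls and the rise are not separate results. Long-range contacts rose in Ter, to 34.0% ± 0.445 (SD, n = 2) from 19.9%, a mean log2 change of 0.79 against 0.22 outside. All 16 Ter segments rose, 52 in all, in runs from 1 to 200000, 450001 to 2750000 and 3900001 to 4000000, and the highest were 1650001 to 1700000 and 1700001 to 1750000, both at 1.00 (SE 0.11, edgeR adjusted p = 6.5e-06). The median change of all segments was 0.25, 0.14 with TMM and 0.53 with totals that leave out contacts over 1000 kb. With TMM the 16 Ter segments also rose, and the split was 41 higher and 23 lower. TMM also carries the lower ratio of origin to terminus in stationary cells, so it is not separate support for the rise in Ter. The count was 28 without stationary replicate 0 and 28 for the class of 200 to 800 kb, 25 higher and 3 lower. It was 21 in a fit of only the 2 groups, when the Ter mean was still 0.79. Without low coverage bins the count was 32, 5 of them in Ter, and the mean was 0.25 in Ter against 0.22 outside. The rise was then about as large outside Ter as in it, but that filter takes out most Ter bins.

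Local contacts in stationary cells rose in 210 bins and fell in 230, and 268 changed without stationary replicate 1. Ter held 109 of the falls and 0 rises, with a median change of -0.22, but with TMM it held 60 rises and 4 falls, with a median of 0.15. Named rises were 2730001 to 2740000 at the chaperone gene clpB and the ribosome hibernation gene raiA (0.56 and 0.46), 2840001 to 2850000 at the formate hydrogenlyase genes hycA to hycI (0.52 and 0.49), 230001 to 235000 at dnaQ (0.48), 245001 to 250000 at the DNA polymerase gene dinB (0.48), 3425001 to 3430000 at rrsD (0.45), hybO (0.45), mutS (0.45) and gcvP (0.44), and all 10 passed with TMM. Named falls were 1195001 to 1200000 at intE of the e14 prophage (-0.70), 3915001 to 3920000 at the ATP synthase operon (-0.65, SE 0.07, edgeR adjusted p = 4.2e-07), 2100001 to 2110000 in the wbb and rfb sugar genes (-0.64 and -0.53), 3795001 to 3800000 at waaL (-0.53), 1220001 to 1225000 at the minCDE division genes (-0.53), 1210001 to 1220000 at ycgZ (-0.53 and -0.52), 1180001 to 1185000 at the spermidine transport genes potABCD (-0.50) and 1230001 to 1235000 at umuDC (-0.50). Of these, 6 were bins of locally low coverage and 3 passed with TMM, among them the ATP synthase operon. TMM also carries the ratio of origin to terminus, 1.05 in stationary against 1.85 in exponential cells. Passing with TMM is thus not separate support for falls near the origin, such as that at the ATP synthase operon. The turn of the Ter median with TMM cannot be told apart from copy number.

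No list changed as a whole in stationary cells by the main scaling. Ribosomal RNA operons had 5 higher places and 0 lower of 7, with a mean of 0.07, but a higher bin in 2 and a lower bin in 2 with TMM, with a mean of -0.19. Their mean was 0.17 without locally low bins (rotation permutation p = 0.029) and 0.17 without low coverage bins (rotation permutation p = 0.075). Values at ribosomal RNA operons may also depend on how reads from these repeats were assigned, which is not known. Prophages had 0 higher and 4 lower of 9, with a mean of -0.15 (rotation permutation p adjusted 0.156), but a higher bin in 2 and a lower bin in 1 with TMM, with a mean of -0.06, and the mean was also -0.06 without low coverage bins. H-NS silenced loci had 6 higher and 9 lower of 19, stationary phase genes 4 and 6 of 17, with rpoS (0.43), osmY (0.27) and the place of raiA higher and that of bolA lower (-0.27), ribosomal protein operons 2 and 5 of 13, and small RNA and envelope genes 1 and 1 of 8, ssrS (0.36) and lpp (-0.28). The lower places of the ribosomal protein list included the ATP synthase gene atpB (-0.65). Flagellar operons had 0 and 2 of 5, with a mean of -0.15 that was 0.18 with TMM. Adjusted over the list alone, ribosomal protein operons had 1 and 5 and flagellar operons 0 and 1, and the other lists had the same counts. The adjusted rotation p of the lists other than prophages ranged from 0.69 to 0.80. With TMM the H-NS silenced loci had a mean of -0.19 (rotation permutation p = 0.0011, the smallest the rotations allow), but without low coverage bins it was 0.04, with a higher bin in 6 places and a lower bin in 3. Also with TMM, stationary phase genes had a higher bin in 8 places and a lower bin in 3, with a mean of 0.11 (rotation permutation p = 0.042), and small RNA and envelope genes in 6 and 1.

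The RNA of stationary cells was concentrated in few places, and 15 bins held 62.6% of the mean signal. The bin of ssrA, the transfer-messenger RNA, held 29.1% (32.8% and 25.3% in the 2 libraries), followed by the bins of the acid shock gene asr with 8.70%, the chaperone genes dnaK and dnaJ with 6.74%, the regulatory RNA csrB with 4.29%, clpB with 2.50% and the RNase P RNA rnpB with 2.00%. Next were the bins of rmf and ompA with 1.43%, the phage shock operon pspABCDE with 1.41%, dps and ompX with 1.22%, pspG with 1.18%, groS and groL with 0.974%, wrbA with 0.855%, the heat shock sigma factor gene rpoH with 0.763%, infC and rplT with 0.733% and the small RNA genes csrC and spf with 0.707%. Single bins differed between the 2 libraries, as at clpB with 3.65% and 1.29%, dps and ompX with 1.84% and 0.567%, rpoH with 1.22% and 0.287% and csrC and spf with 0.281% and 1.16%. Between the libraries, Spearman's rho across bins was 0.924. Among the lists, 8 of 17 stationary phase places, 6 of 13 ribosomal protein places and 4 of 8 small RNA and envelope places were in the top 5% of bins (rotation p adjusted 0.00754, 0.00754 and 0.0151). Ribosomal RNA operons, H-NS silenced loci and flagellar operons had 0 and prophages 1 of 9 (adjusted 1.0).

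Places with more RNA had more local contacts in the stationary map. Across bins, which are not independent replicates, Spearman's rho between RNA signal and balanced contact at 10 to 50 kb, over its running median, was 0.30 (rotation p = 0.0011, the smallest of 889 rotations). The exponential map, set against the same stationary RNA, gave 0.41, with the same p. Domain borders did not gather at RNA peaks. Of 30 borders in the stationary map 5 lay within 10 kb of the top 5% of bins, against 6.50 expected by rotation (permutation p = 0.63, two-sided), and 3 did so without RNA replicate 1. Of the 30 borders, 12 lay within 10 kb of 1 of the 31 borders of the exponential map, and borders called from 1 stationary replicate lay near those from the other in 16 of 33 cases.

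Medium and temperature were compared in wild type. Between LB and minimal medium at 30 °C, edgeR placed 0 long-range segments past the threshold, with 0 at an unadjusted p under 0.05 and 0 by DESeq2. With TMM 30 were higher and 25 lower, with totals that leave out contacts over 1000 kb the median moved from 0.03 to 0.21, 12 were lower for the class of 200 to 800 kb, and 1 was lower without low coverage bins. In LB the share of Ter contacts at 100 to 280 kb fell, in 14 of its 16 segments with a mean of -0.53, and that over 1000 kb rose in 12. Between 22 and 30 °C the Ter mean was 0.23 and the mean outside 0.09, with 0 segments past the threshold by edgeR, 12 higher at an unadjusted p under 0.05 and 9 higher by DESeq2. The median of all segments was 0.10, and 0.20 with totals that leave out contacts over 1000 kb. Between 37 and 30 °C in LB, which was not planned, edgeR placed 0 segments past the threshold, with 0 at an unadjusted p under 0.05 and 0 by DESeq2.

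Contacts per bin near the origin over those near dif, the site where chromosome dimers are resolved, differed between media and growth phases. The ratio was 1.85 ± 0.219 (SD, n = 3) in wild type in minimal medium at 30 °C, 1.57 ± 0.0368 (SD, n = 2) at 22 °C, 2.94 ± 0.195 (SD, n = 2) in LB at 30 °C, 3.42 ± 0.344 (SD, n = 2) in LB at 37 °C and 1.05 ± 0.00279 (SD, n = 2) in stationary cells. It was 5.95 ± 0.661 (SD, n = 2) in hupAB, where both libraries lay above both of wild type, and 2.30 ± 0.00812 (SD, n = 2) in hns, below both of wild type. An exact test of 2 against 2 libraries cannot give a p under 0.333.

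**Figure D3:**
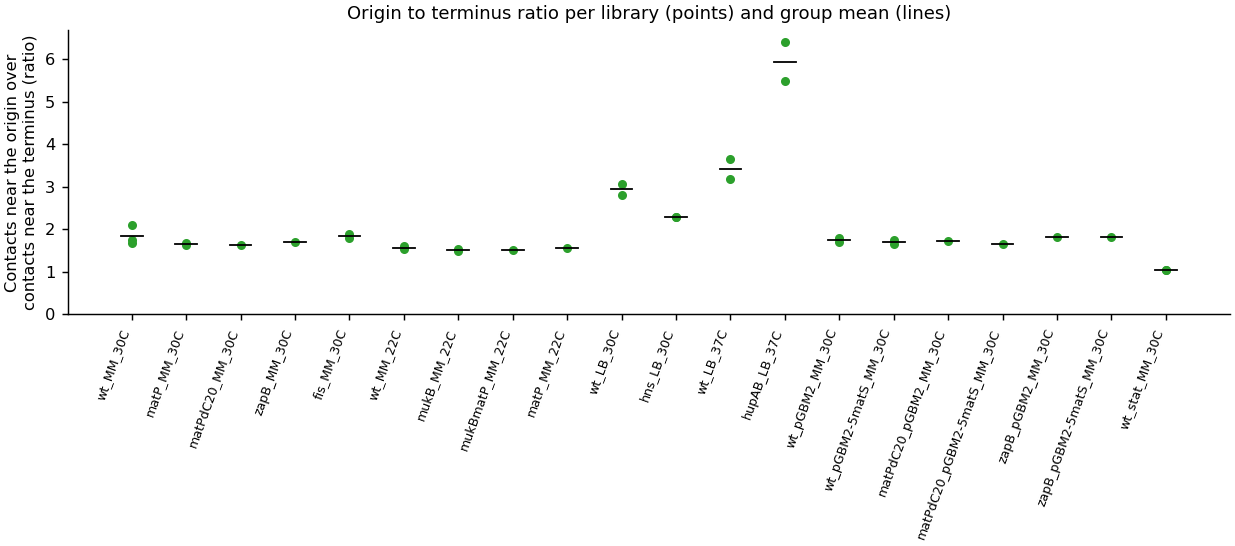
Ratio of contacts per bin within 250 kb of the origin to that within 250 kb of dif, with one point per library and a line at the mean of each group. Stationary cells are at 1.05 and hupAB at 5.95.

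The plasmid strains ask whether matS sites carried on a plasmid change contacts of Ter. Between pGBM2 with 5 matS sites and pGBM2 in wild type, edgeR placed 0 long-range segments past the threshold, with 1 at an unadjusted p under 0.05 and 0 by DESeq2, and the Ter mean was 0.15 against 0.01 outside. In zapB the same comparison gave 0.15 in Ter and in matPdC20 -0.01, each from 1 library against 1. The matPdC20 pair differs in file layout, tabbed with pGBM2 and spaced with 5 matS sites, so plasmid and layout cannot be told apart there. The zapB pair is spaced and the wild-type libraries tabbed. The zapB files still differ in the contact of the first bin with the last, over the median of adjacent bins. That value was 1.34 with pGBM2 and 23.7 with 5 matS sites, so a difference in processing is not excluded there either. The contacts of the first bin of the matrix were 2.50 to 10.9998 times those of its neighbours in 5 plasmid libraries. In wild type its contacts with Ter, over the expectation from bin totals, were 1.48 and 1.85 with 5 matS sites (1.66 ± 0.258, SD, n = 2) and 1.03 and 1.05 with pGBM2 (1.04 ± 0.00935, SD, n = 2), with an exact permutation p of 0.333, the smallest possible. In libraries without a plasmid this value was 0.431 to 0.931.

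**Figure D4:**
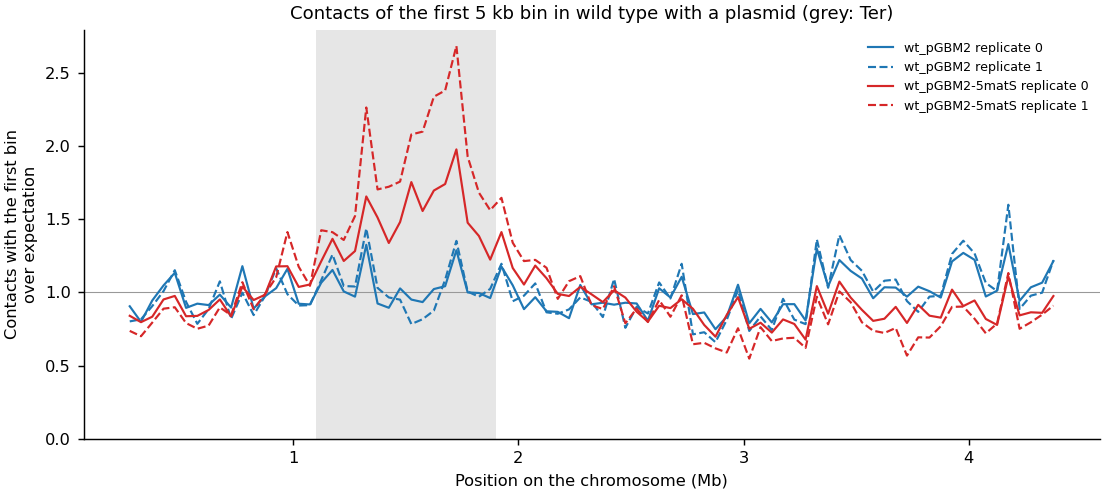
Contacts of the first 5 kb bin with the chromosome, over the expectation from bin totals, along the chromosome in Mb with Ter in grey. Lines are the 4 wild-type libraries with a plasmid, and both with 5 matS sites, at 1.48 and 1.85 over Ter, lie above both with pGBM2.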

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

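Of the tests in this part, those of a wild-type mixture, of plasmid reads beside the first bin's own contacts, of matS sites bringing the plasmid to Ter, of 5 matS sites weakening the separation of Ter and of copy number in stationary cells were chosen only after the result was seen.

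Both libraries labelled mukB kept contacts of the mukB bin, at 0.793 and 0.839 of the bins around it, where mukBmatP had 0.131. A culture made up mostly of wild-type cells would need a wild-type share of 92.5% to give that bin, and the loss of long-range contacts outside Ter would then be small. That loss was 93.3% of the one in mukBmatP, or 71.3% and 115% in the single libraries, which argues against a mixture as the whole cause. Contact across the bin, over that of pairs around it, gave no sign of a deletion of part of it, at 0.871 in 1 library and 1.87 in the other, against 1.198 to 2.00 in libraries not labelled mukB. A short deletion is not excluded, since mukBmatP itself reached only 2.21. Another allele, such as a point mutation or an insertion, was not tested, since the maps hold no sequence.

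The first bin of the matrix, which holds the start of the deposited coordinates, had more contacts than its neighbours in 5 plasmid libraries and in no library without a plasmid, where the ratio was 0.957 to 1.07. The ratios were 9.42 and 7.42 in wild type with pGBM2, 10.9998 and 7.54 in wild type with 5 matS sites and 2.50 in matPdC20 with pGBM2. Amplification of the first 5 kb is argued against, because 37.97% or more of the bin's contacts lay over 1000 kb away, against at most 24.2% in its neighbours. Plasmid reads with no preference along the chromosome would give about 57.0%, the share of bins at that separation, and the highest library had 56.7%. Set beside the bin's own contacts, the excess alone had 53.0% to 63.1% at that separation, consistent with plasmid reads, and the 3 plasmid libraries in the spaced layout showed no excess (0.998 to 1.05).

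With 5 matS sites, contacts of that bin with Ter were above those with pGBM2 in both wild-type libraries. Mapping of a cloned fragment to its own Ter bins is argued against, since without the 5 highest Ter bins the values were 1.47 and 1.82, against 1.02 and 1.03 with pGBM2. Whether matS sites may bring the plasmid to Ter stays open, as 2 libraries against 2 cannot give an exact permutation p under 0.333. The plasmid's sites could also weaken the separation of Ter from its flanks, where contact was higher by 0.30 in wild type, 0.20 in zapB and 0.04 in matPdC20 (exact permutation p = 0.0833 within strains, the smallest of 24 arrangements). The matPdC20 pair also differs in file layout. The zapB pair differs in the contact of the first bin with the last, at 1.34 with pGBM2 and 23.7 with 5 matS sites.

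Without low coverage bins, long-range contacts of stationary cells rose about equally in Ter and outside, with mean log2 changes of 0.25 and 0.22. That filter takes out most Ter bins. With all bins, the rise of long-range contacts in Ter, 0.79 against 0.22 outside, came with an origin to terminus ratio near 1.05. Whether a change of copy number could give it stays open, as 2 measures on balanced maps differ. The share at 280 to 1000 kb in Ter over its outside changed by 0.0028 from minimal medium to LB at 30 °C, where the stationary slope needed -0.48. Contact within Ter at 280 to 600 kb changed by -0.24, where it needed -0.68. In group means of wild type without a plasmid, it went down as the origin to terminus ratio went up. It was 0.20 in stationary cells (0.03 and 0.36 in the libraries), -0.50 at 22 °C and -0.64 at 30 °C in minimal medium. In LB it was -0.88 at 30 °C and -1.04 at 37 °C. Wild type with pGBM2 kept this order, at -0.60 with a ratio of 1.74. Wild type with 5 matS sites broke it, at -0.69 with a ratio of 1.71, where wild type without a plasmid at 30 °C had 1.85. Mutants also broke the order, with -0.80 in hupAB at a ratio of 5.95 and -1.16 in hns at 2.30. A loss of the state that MatP maintains is a candidate explanation, as the profile resembled that of matP at 22 °C, with a Spearman's rho across segments of 0.739 (rotation p = 0.0860 over 92 rotations). It stays open, because MatP was not measured and the correlation was 0.54 outside Ter as well.

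The self-contacts of the bin at 1205001 to 1210000, which no comparison used, were far above those of its neighbours in all 8 spaced files. They were 40.2 times in wild type at 30 °C replicate 2, 46.0 in wild type at 22 °C replicate 0, 61.4 in replicate 0 of those labelled mukB, 12.1 in mukBmatP, 30.7 in matP at 22 °C, 25.8 in matPdC20 with 5 matS sites, 28.1 in zapB with pGBM2 and 27.6 in zapB with 5 matS sites, against 1.14 to 3.07 in the 25 tabbed files.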

How the results depend on the processing

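Totals without contacts over 1000 kb, removal of locally low bins or of the first bin, fits on tabbed files alone and the file layout as a term were chosen only after the data were seen, and the other alternatives were planned. For the results that answer a comparison, 268 of 311 alternative values kept their direction and their side of the threshold, or stayed within 1.5 times a count, 5 were weaker, 7 stronger, 31 moved and 0 reversed. A reversal could not be scored for local counts or for the ratio of origin to terminus, and 0 under both settings was scored as kept. The tally also leaves out means of gene lists and medians of regions, some of which turned sign. Those of at least 0.05 on both sides with TMM were H-NS silenced loci in hns (0.21 to -0.11), small RNA and envelope genes in hupAB (0.05 to -0.13), and in stationary cells flagellar operons (-0.15 to 0.18), ribosomal RNA operons (0.07 to -0.19) and the local median of Ter (-0.22 to 0.15). Smaller values turned as well, among them prophages in hns (0.14 to -0.02), in hupAB flagellar operons (to -0.30), stationary phase genes (to -0.09) and H-NS silenced loci (to -0.05) with TMM, and in stationary cells H-NS silenced loci (-0.07 to 0.04) without low coverage bins. No paired analysis was made, because the groups compared share fewer than 2 replicate numbers in the labels. Contact within Ter was lower in replicate 1 than in replicate 0 in every LB group, as in wild type at 30 °C (-0.74 and -1.01) and hupAB (-0.79 and -0.82). In minimal medium, fis and stationary cells went the other way. A batch shared between replicates of different LB groups is therefore not excluded. With the file layout as a term beside the groups, counts stayed within 1.5 times those without it, among them 86 long-range segments in the libraries labelled mukB and 12 in matP at 22 °C, and 0 stayed 0 (mukBmatP against the libraries labelled mukB had 6 at an unadjusted p under 0.05). The test of plasmid contacts with its alternatives, and bounds of Ter from matS motifs, were not run. Counts were not thinned, so what depth limits is not known.

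Without low coverage bins the long-range counts were 2 in matP at 30 °C, 0 in matP at 22 °C by edgeR (3 at an unadjusted p under 0.05), 32 in stationary cells and 1 in LB against minimal medium, where 133 of the 160 Ter bins were removed by construction. For the other settings the cause was not tested. With TMM they were 59 in fis, 33 in hns and 55 in LB against minimal medium, 30 higher and 25 lower. The stationary split was 41 higher and 23 lower instead of 52 and 0, and that of local contacts in fis 6 and 56 instead of 17 and 28. Local counts with TMM were 328 in hns and 502 in hupAB. With totals without contacts over 1000 kb they were 37 in fis, 0 in matP at 22 °C by edgeR (10 at an unadjusted p under 0.05) and 91 in stationary cells. In fits of only the groups compared they were 20 in the libraries labelled mukB, 0 in hupAB by edgeR (9 at an unadjusted p under 0.05), 21 in stationary cells, and for local contacts 28 in fis and 290 in hns. On tabbed files alone the libraries labelled mukB had 0 by edgeR (52 at an unadjusted p under 0.05). For the class of 200 to 800 kb they were 49 in mukBmatP against wild type, 1 in hns, 28 in stationary cells and 12 in LB against minimal medium. DESeq2 gave 2 in hns and 9 between 22 and 30 °C. Local contacts at 10 to 100 kb gave 80 in fis and 299 in hupAB. With 100 kb windows the median origin to terminus ratio over the 20 groups was 1.84 against 1.72. Groups moved unevenly, as from 5.95 to 6.88 in hupAB and from 1.85 to 2.01 in wild type in minimal medium at 30 °C. Over all alternatives, 22 of 60 group values were scored as moved.

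Leaving out each library in turn gave long-range counts of 17 to 35 in matP at 30 °C (34 with all), 27 to 90 in fis (89), 70 to 88 in the libraries labelled mukB (86), 0 to 7 in matP at 22 °C (11), 67 to 69 in mukBmatP against wild type (78), 68 to 83 in hupAB (82) and 28 to 67 in stationary cells (52). Local counts were 10 to 52 in fis (45), 28 to 146 in hns (192), 83 to 126 in hupAB (191) and 268 to 446 in stationary cells (440). The Ter difference ranged from 0.492 to 0.503, the correlation of RNA with local contacts from 0.273 to 0.351 and the borders at RNA peaks from 3 to 6. With 1 library left in a group, it was assumed to vary like the others.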

Other observations

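Apart from the changes at the deleted genes, the tests and values in this part were chosen only after the data were seen.

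Local contacts were lower in fis, hns and hupAB alike in 5 bins, and higher in 0. They began at 1305001, 3910001, 3920001, 3935001, beside rrsC, and 3945001. With TMM 6 bins were lower in all 3 mutants, of which only 1305001 was among these 5. The bin at 1305001 to 1310000, at oppF of the oligopeptide transporter and beside tonB, the energy transducer of outer membrane uptake, fell by 0.51 in fis, 0.40 in hns and 0.39 in hupAB on the log2 scale, each against its own wild type, and by 0.89, 0.56 and 0.98 with TMM. Whether the falls differ between the mutants was not tested.

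The stationary RNA libraries ranked bins alike but differed at several stress loci. The bin of pspABCDE, the phage shock operon, held 0.124% of the signal in replicate 0 and 2.77% in replicate 1, and that of pspG, of the same regulon, 0.042% and 2.38%. The regulatory RNA csrB went the same way, with 1.17% and 7.57%, and dnaK and dnaJ the other way, with 9.88% and 3.43%. Ter held 17.7% of the RNA signal and 17.2% of the bins.

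Local contacts at the deleted genes themselves went both ways. The change was 0.15 at fis in fis (edgeR adjusted p = 0.075), -0.12 at hns in hns (0.241), 0.22 at hupA in hupAB (0.00436) and -0.18 at hupB in hupAB (0.0187). Contact of the first bin with the last, over the median of adjacent bins, was 19.3 to 31.1 in 6 of the spaced files, 1.33 to 1.34 in the other 2 and 1.00 to 2.30 in the tabbed files.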
